A study of Lactococcus cremoris subsp. cremoris MG1363 with 8 samples.

How the data were processed

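Total RNA of Lactococcus cremoris subsp. cremoris MG1363, a laboratory strain of a lactic acid bacterium used in dairy fermentation, was measured on 8 one-colour Agilent arrays. Per the labels, 3 arrays held cells growing with glucose (reference), 3 held cells sampled 10 min after glucose depletion, and 2 held cells sampled 60 min after depletion. The RNA was extracted with hot phenol and labelled with Cy3 from random hexamers. All 8 arrays sat on 1 slide and were scanned at 1 time. Row 1 of the slide held reference replicates 1 and 2, 10 min replicate 1 and 60 min replicate 1; row 2 held reference replicate 3, 10 min replicates 2 and 3 and 60 min replicate 2. The labels give optical densities at 450 nm of 0.15, 0.18 and 0.21 for the reference samples, where the series description gives 0.15 alone, so by their labels these samples were not taken at 1 density. The labels do not say whether replicates were separate cultures or samples of 1 culture over time, so the p-values measure the spread between these samples, which may be partly technical.

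Per the file headers, the values used are processed signals of Agilent Feature Extraction 10.5.1.1, a fluorescence intensity on a linear scale, background-subtracted and spatially detrended within each array and not scaled between arrays. The deposited files also hold median spot and background intensity, and other columns, flags that mark control spots, saturation, outlier spots and spots well above background. The authors also deposited a table of normalised intensity on a linear scale with a floor of 50, in which all 8 columns had nearly equal quantiles. Each of its columns correlated best with its own array, at r = 0.987 to 0.996 over spots. The authors' values were used as an alternative.

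Each array held 15744 spots, of which 15208 were not controls and carried 13867 probes, 1341 of them spotted more than once. Probe names gave 2434 chromosomal genes by locus tag, 2401 of them with 5 probes, and also pseudogenes, tRNA, rRNA and phage genes. Spots with an outlier flag (0.230% to 2.08% per array) were left out, and no spot was saturated. Well above background were 87.7% to 95.5% of non-control spots per array, and the number of arrays limits the precision. The median absolute log2 difference between duplicate spots was 0.10 to 0.12, and between replicate arrays it was 0.14 in the reference, 0.25 at 10 min and 0.34 at 60 min. Correlations between arrays of a group were 0.974 to 0.993 over genes.

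Log2 processed signals were scaled to the 75th percentile of the non-control spots of each array. Spots were averaged per probe and probes per gene. A probe with every spot removed on an array (876 probe and array values) took the mean of its group's other arrays plus the deviation of the gene's other probes on that array. Genes were kept when at least 1 probe was well above background on at least 2 arrays, which removed 50 of 2539 genes and left 2489, among them 2432 chromosomal and 57 phage genes.

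limma 3.58.1 in R 4.3.3 fitted the 3 group means with lmFit and eBayes, and Benjamini-Hochberg adjusted p-values under 0.05 were called changed. Data were read with the data.table package, version 1.17.8, and plots were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. The comparisons were 10 min against reference, 60 min against reference and 60 min against 10 min. A second scaling subtracted the mean log2 signal of 7 of the 10 Agilent E1A spike-in probes, those well above background on all arrays. Spike-ins are foreign RNAs added in a fixed amount, and the labels do not state at which step they were added. Signal medians per probe class were compared with two-sided exact permutation tests. With 3 arrays against 3, or 2 against 3, these exact tests cannot go below p = 0.10, so the 5 starved arrays were also compared with the 3 reference arrays over 56 splits, where the smallest p is 0.0179. Those p-values were adjusted over 12 quantities.

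Of 23 gene lists fixed before the data were examined, 22 covering metabolism, uptake, translation, stress, replication, cell wall, respiration, regulators and transposases had 0 matched members. The files do not pair locus tags with gene names, and the 2360 genes of the reference annotation, from another strain, matched 0 locus tags. Only the list named prophage genes could be tested, with 57 measured members. These were all probe sets named for phages, among them the lytic phage sk1. Prophage genes given only by a chromosomal locus tag could not enter it. The list was tested with limma's camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. Named genes were to be, in each comparison, the 8 largest rises and 8 largest falls with a gene symbol, an adjusted p under 0.05 and no overlap between groups, the 3 list members with the smallest p, and the 3 largest changes each way without a symbol. As no names were paired with the tags, 2 locus tags that rose and 2 that fell are given. Phage genes picked by the rule that lay at background are given as counts.

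The replicate numbers were checked for pairing. Deviations from the group mean correlated between reference and 10 min arrays of the same number at r = 0.49, 0.11 and 0.57 over genes, so a fit with the replicate number as a block was run. They correlated at 0.37 and 0.05 between reference and 60 min arrays and at 0.65 and -0.02 between 10 min and 60 min arrays. Fits with the slide row as a block and within each row were run as well.

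The procedure was tested on simulated data with 200 changed genes among 2489. In 10 min against reference it found 31.3%, 79.1% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, and 7 of 146 calls were of unchanged genes. In 60 min against reference it found 25.4%, 58.2% and 93.9%, and 13 of 131 calls were of unchanged genes. The simulated noise was independent between arrays and had the same spread in all groups. In the data replicate arrays differed more at 10 and 60 min than in the reference, and far more genes were called. These shares therefore do not give the error rate of the real calls.

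Alternatives fixed before the data were examined were quantile, median and spike-in scaling, the 75th percentile over probes well above background, the authors' table, normexp background correction, no filter or a filter on all 8 arrays, probe medians, a trended and robust variance, only the groups compared, the blocks, a stricter threshold, other set tests and leaving out each array. For normexp, the median spot signal stood in for the mean spot signal, which the files do not hold. Added after the data were seen were rRNA scaling, keeping outlier spots, only probes well above background on all arrays, the fits within each slide row, and all alternatives for the class signals and for the limits of falls. Where a gene given by name, or 1 TP901-1 gene, had probes not well above background in the later group, every probe signal there was set per array to at least the lowest signal well above background, which gives a lower limit of the fold.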

Results

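The arrays measured RNA of MG1363 growing with glucose (reference, n = 3) and at 10 min (n = 3) and 60 min (n = 2) after abrupt glucose depletion. The question was how transcript levels differ after the sugar runs out. The median processed intensity of chromosomal probes was 12990, 11687 and 12263 on the 3 reference arrays, 4533, 8309.5 and 6858 on the 10 min arrays, and 2062 and 2816 on the 60 min arrays. Because the common level of the genes differed between groups, the main counts of changed genes are given under both scalings. The 75th percentile scaling compares genes with each other on an array. Spike-in scaling compares them with RNA added in a fixed amount. Counts of non-overlapping genes, of probe signs and of fits with or within slide rows use the 75th percentile scaling alone. The chance share given beside the non-overlapping genes holds for a single gene. Genes share the shifts of an array, and this scaling moved background spots too, so an excess over that share is not a test.

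Against the spike-ins, the signal of protein-coding transcripts was lower in starved cells. The median log2 signal of chromosomal probes was 13.52 ± 0.16 (SD, n = 3) in the reference, 12.66 ± 0.45 (n = 3) at 10 min and 11.30 ± 0.55 (n = 2) at 60 min. The 10 min mean was 55.0% of the reference level (log2 difference -0.86) and the 60 min mean was 21.5% (-2.22). tRNA probes, which measure the adaptors of translation, went from 17.26 ± 0.12 to 16.15 ± 0.22 and 15.24 ± 0.43, or 46.4% and 24.7% of the reference level. Pseudogene probes differed by -0.73 at 10 min (-0.47 without 10 min replicate 1) and -1.43 at 60 min (-0.95 without 60 min replicate 1). The rRNA probes, from the RNA of the ribosome, were at 18.56 ± 0.05, 18.75 ± 0.05 and 18.81 ± 0.29, differences of +0.19 and +0.26. The 60 min arrays differed in rRNA, as the value was +0.47 without replicate 1 and +0.05 without replicate 2, so its size at 60 min is not settled. The size also rests on the mean over all spike-ins used. Before scaling, the rRNA median differed by +0.12 at 60 min. The brightest and next brightest spike-ins, close to it in signal, differed by +0.07 each, and the dimmer ones by -0.26 to -0.16.

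In exact permutation tests of the 5 starved arrays against the 3 reference arrays, the chromosomal median differed by -1.40 (p = 0.0357, adjusted p = 0.0857). The tRNA median differed by -1.47 (exact p = 0.0179, the smallest these splits can give, adjusted p = 0.0857), and the rRNA median by +0.22 (exact p = 0.0714, adjusted p = 0.143). All 5 starved arrays were below all 3 reference arrays for chromosomal, pseudogene and tRNA medians, and no class difference passed the correction. Within an array, the rRNA median minus the chromosomal median was larger by 1.05 at 10 min and by 2.48 at 60 min than in the reference. This ratio shows unequal change of the signals and not which class moved. A detector plateau for rRNA, weighed below, could also give it without unequal change of the RNA. The difference in the chromosomal median was -1.38 at 10 min and -2.61 at 60 min within row 1 of the slide (2 reference arrays and 1 of each starved group), and -0.60 and -1.83 within row 2 (1 reference, 2 at 10 min and 1 at 60 min). The mean spike-in signal before scaling differed by -0.09 at 10 min (-0.05 without reference replicate 2, -0.06 without 10 min replicate 3). At 60 min it differed by -0.13, with -0.29 without 60 min replicate 1 and +0.03 without 60 min replicate 2. The median of the negative control spots lay between 6.50 and 6.74 in the 3 groups.

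**Figure D1:**
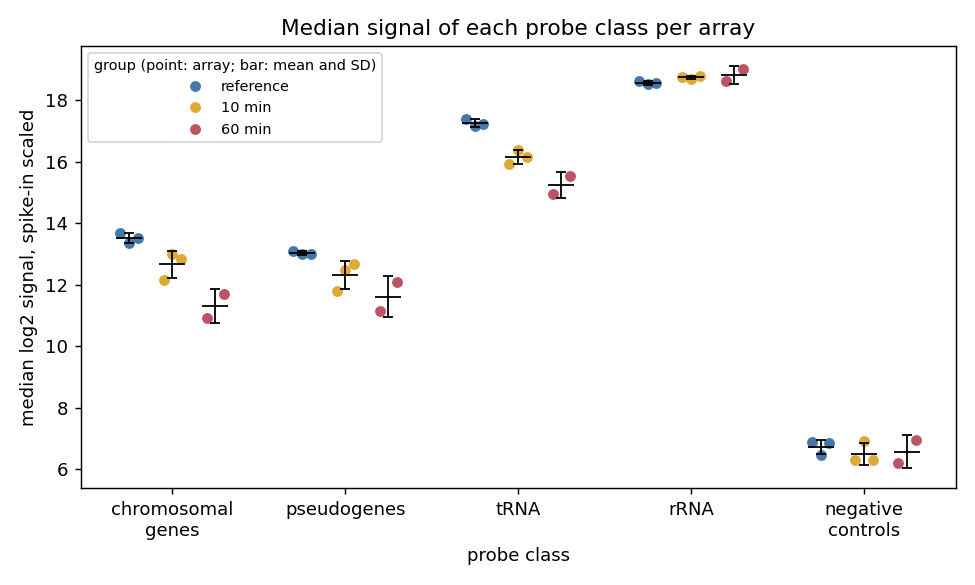
Median log2 signal of chromosomal, pseudogene, tRNA, rRNA and negative control probes after spike-in scaling, per array (points), with the mean and SD of each group (bars), for reference, 10 min and 60 min. Chromosomal medians went from 13.52 to 12.66 and 11.30, while rRNA medians went from 18.56 to 18.75 and 18.81.

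The comparison of 10 min with the reference addressed the early response to glucose depletion. The largest rise was that of llmg_2432, at +5.42 (SE 0.23, n = 3 and 3, adjusted p = 3.1e-06) relative to other genes and +4.76 (SE 0.28) against the spike-ins, a 27.0-fold higher level. The gene llmg_2311 was also higher, by 4.21 (SE 0.33) relative to other genes and 3.55 against the spike-ins, or 11.7-fold. The largest fall was that of llmg_1848, at -3.93 (SE 0.15, adjusted p = 2.5e-06) and -4.60 against the spike-ins, a level at least 24.2-fold lower, with 4 or 5 of its 5 probes well above background per 10 min array. The gene llmg_0973 changed by -2.85 and by -3.50 against the spike-ins, or 11.4-fold lower. All 5 probes of each of these 4 genes moved in the gene's direction on the means of the groups. In llmg_2311 the rise was shared by consecutive locus tags: a run of 5 tags was each at least 4-fold higher relative to other genes, with spike-in values of +2.06 to +4.23. In llmg_1848 a run of 3 tags was each at least 4-fold lower relative to other genes, with spike-in values of -4.60 to -3.82.

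In all, 1143 of 2489 genes changed, 511 higher and 632 lower, of which 220 and 285 changed at least 2-fold. With spike-in scaling 108 were higher and 864 lower, and the median gene was at -0.64, or 64.0% of the reference level. The same 108 genes were higher with both scalings and the same 632 were lower with both. Both scalings shift all genes of an array alike, so this overlap is largely set by the shift and is not independent support. Median scaling gave 725 higher and 505 lower, and scaling on rRNA gave 1385 lower among 1490 changed. The arrays of both groups did not overlap for 1478 genes, or 59.4%, where chance gives 10%. In 98.0% of changed genes every probe had the gene's sign. With the slide row as a block 1293 genes changed. Within row 1 there were 1059, from 1 array at 10 min against 2, and within row 2 there were 192, from 2 against 1.

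Genes that changed stood beside each other along the locus tags. Of the 108 genes higher with both scalings, 79 had a neighbour that was higher too, against a mean of 8.90 when tags were shuffled (permutation p = 1.0e-05, the smallest 100000 shuffles can give, adjusted p = 1.2e-05). They formed 10 runs of at least 3 genes, the longest of 7. Of the 632 genes lower with both scalings, 517 had such a neighbour, against 274 by shuffling (permutation p = 1.0e-05, adjusted p = 1.2e-05), and the longest run held 11 genes. Locus tags follow the chromosome, and bacterial genes often share transcripts with their neighbours. These counts are across genes, which are not independent replicates.

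**Figure D2:**
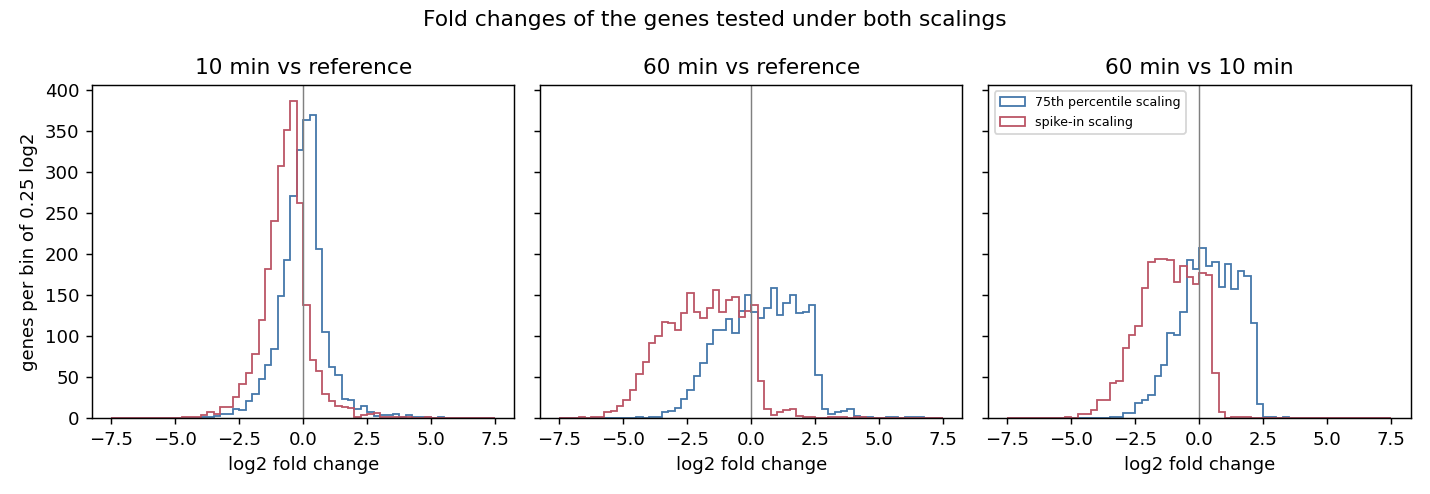
Number of genes per bin of log2 fold change, for the 2489 tested genes in each comparison, with 75th percentile scaling and with spike-in scaling. The median gene was at +0.01, +0.43 and +0.42 with percentile scaling and at -0.64, -1.83 and -1.19 with spike-in scaling.

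The comparison of 60 min with the reference addressed the later state. The largest rise was that of llmg_2311, at +6.69 (SE 0.37, n = 2 and 3, adjusted p = 6.8e-06) relative to other genes and +4.42 (SE 0.36, adjusted p = 8.2e-07) against the spike-ins, or 21.5-fold. The gene llmg_2432 was higher by 5.29 and by 3.03 against the spike-ins, or 8.15-fold. The largest fall was that of llmg_0973, at -4.43 (SE 0.30) and -6.69 (SE 0.48, adjusted p = 7.1e-07) against the spike-ins. On the 60 min arrays 2 and 4 of its 5 probes were well above background, so its level there is given as at least 95.7-fold lower. The gene llmg_1848 was at -2.77 and -5.06, or at least 32.8-fold lower against the spike-ins. Relative to other genes, runs of consecutive tags changed by at least 4-fold held 6 genes at llmg_2311, 6 at llmg_2432, 3 at llmg_1848 and 3 at llmg_0973. Against the spike-ins the runs spanned +0.40 to +4.42 at llmg_2311 and -0.25 to +3.03 at llmg_2432, so that not every member passed the test there (largest adjusted p in the limma fit 0.294 and 0.883). They spanned -5.06 to -4.35 at llmg_1848 and -6.69 to -4.92 at llmg_0973.

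With 75th percentile scaling 1977 genes changed, 1202 higher and 775 lower, of which 920 and 515 changed at least 2-fold. With spike-in scaling 44 were higher and 1741 lower, and the median gene was at -1.83, or 28.0% of the reference level. Of the 1202 genes higher relative to other genes, 455 were lower against the spike-ins and 44 were higher. The 775 lower genes were lower with both, which the common shift between the scalings largely sets. Quantile scaling gave 996 higher and 993 lower, the authors' values 971 and 994, and rRNA scaling 41 and 1953. Against the spike-ins 1132 genes were at least 4-fold lower with every 60 min signal set to at least the lowest one well above background. The arrays of both groups did not overlap for 2166 genes, or 87.0%, where chance gives 20%. In 93.6% of changed genes every probe had the gene's sign. With the slide row as a block 2045 genes changed, with 1821 within row 1 (1 array at 60 min against 2) and 1287 within row 2 (1 against 1). The last fit took its spread from the pair of 10 min arrays of that row. Of the 44 genes higher with both scalings, 29 had a neighbouring tag that was higher too, against 1.47 by shuffling (permutation p = 1.0e-05, adjusted p = 1.2e-05), and the longest run held 6 genes. Of 773 chromosomal genes lower with both scalings, 642 had such a neighbour, against 397 by shuffling, and the longest run held 15 genes.

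The comparison of 60 min with 10 min addressed what moved as starvation went on. The gene llmg_2311 was higher relative to other genes (+2.48, SE 0.37, n = 2 and 3, adjusted p = 8.1e-04), and against the spike-ins its value was +0.87 (SE 0.36, adjusted p = 0.0545). The gene llmg_2432 was lower against the spike-ins, at -1.73 (adjusted p = 4.0e-04), with -0.13 (adjusted p = 0.667) relative to other genes. The gene llmg_0973 was lower with both, at -1.58 and -3.19, with a limit of -3.08 against the spike-ins for its probes at background. The gene llmg_1848 was higher relative to other genes, at +1.16, where its spike-in value was -0.46 (adjusted p = 0.347). Percentile scaling moved the negative control spots by +1.67 here, more than this gene, so its value does not show a recovery. In all 1745 genes changed, 1161 higher and 584 lower, of which 834 and 303 changed at least 2-fold. Spike-in scaling gave 3 higher and 1431 lower, with the median gene at -1.19, or 43.9% of the 10 min level. Of the 1161 genes higher relative to other genes, 156 were lower against the spike-ins. Quantile scaling gave 830 higher and 875 lower, the authors' values 803 and 870, and rRNA scaling 3 and 1553. The arrays of both groups did not overlap for 1923 genes, or 77.3%, where chance gives 20%. With the slide row as a block 1863 genes changed, with 1266 within row 2 (1 array at 60 min against 2) and 1232 within row 1 (1 against 1). Every fit within row 1 took its spread from the pair of reference arrays of that row. Replicate arrays differed least in the reference (0.14, against 0.25 at 10 min and 0.34 at 60 min), so the row 1 counts may be too high.

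Early and late changes overlapped. With 75th percentile scaling 386 genes were higher at both times, where independent calls give 247, and 463 were lower at both times, where independent calls give 197. Another 43 were higher at 10 min and lower at 60 min, and 18 were lower and then higher. Both comparisons share the reference arrays. The fold changes correlated at r = 0.67 over genes, against 0.44 simulated for unchanged groups sharing the references, and their covariance was 0.94 against 0.03. Of the 511 genes higher at 10 min, 194 rose further by 60 min, 133 fell back and 184 passed neither test, and of the 632 lower genes 194 fell further, 173 rose back and 265 passed neither. Against the spike-ins, 2 of the 108 higher genes rose further, 71 fell back and 35 passed neither test, while 627 of the 864 lower genes fell further, 0 rose back and 237 passed neither. With this scaling 38 genes were higher at both times, where independent calls give 1.91, and 852 were lower at both, where they give 604. Another 18 were higher and then lower, and 0 were lower and then higher.

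**Figure D3:**
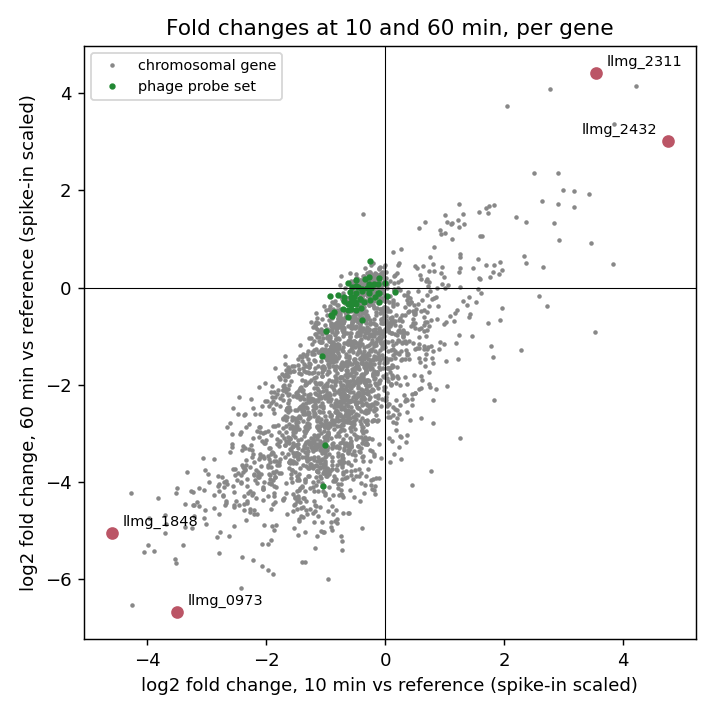
Log2 fold change at 60 min (vertical axis) against that at 10 min (horizontal axis), both relative to the reference with spike-in scaling, for each tested chromosomal gene (grey) and phage gene (green). With this scaling 38 of the 108 genes higher at 10 min were also higher at 60 min, and llmg_2311, llmg_2432, llmg_1848 and llmg_0973 are marked.

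**Figure D4:**
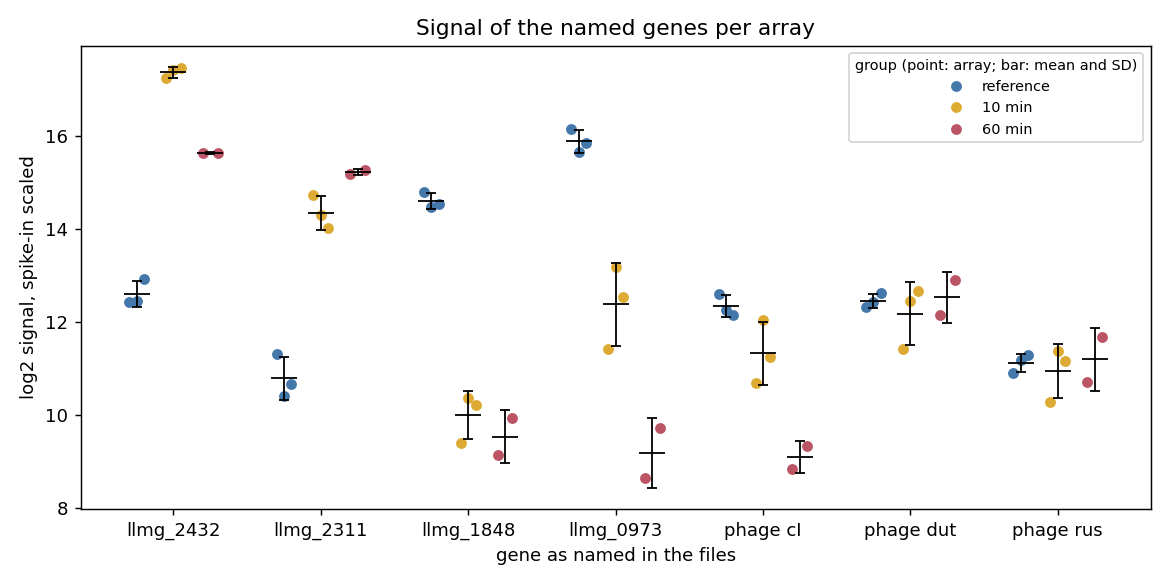
Log2 signal after spike-in scaling of llmg_2432, llmg_2311, llmg_1848, llmg_0973 and the phage genes cI, dut and rus on each array (points), with the mean and SD (bars) of the reference, 10 min and 60 min groups. Against the spike-ins, llmg_2311 was 11.7-fold and 21.5-fold higher and llmg_0973 was 11.4-fold and at least 95.7-fold lower at 10 and 60 min.

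The array also held probes for genes of bacteriophages, among them the lactococcal phages sk1, which is lytic, and TP901-1, which is temperate. Whether the cultures carried these phages was not tested, so signal on their probes is not shown to be phage transcript. Few were detected throughout: 47 of 52 sk1 genes, 28 of 35 TP901-1 genes and 13 of 18 genes given by a symbol had no probe well above background on all arrays. The gene cI, which in temperate phages encodes the repressor of the lytic genes, was at -0.98 at 60 min relative to other genes (adjusted p = 0.0035) and at -3.24 against the spike-ins (adjusted p = 9.7e-06). Of its 5 probes, 2 were well above background on all arrays, so its level at 60 min is given as at least 7.51-fold lower. With normexp background correction its value at 60 min relative to other genes was -0.39 (limma adjusted p = 0.0849), and within row 2 of the slide, with 1 array against 1, it was -0.83 (limma adjusted p = 0.149). The adjusted p over its alternatives ranged from 9.3e-07 to 0.149. At 10 min cI was at -0.36 (adjusted p = 0.175), at -1.02 against the spike-ins (adjusted p = 0.0394), and at -0.58 relative to other genes without 10 min replicate 2 (adjusted p = 0.0184), with a range of 0.0074 to 0.931 over its alternatives. The genes dut, for a dUTPase, and rus, for a Holliday junction resolvase, had every probe above background on all arrays. At 60 min they were higher relative to other genes, at +2.33 and +2.34. Both were at +0.07 against the spike-ins, and with rRNA scaling they were at -0.19 and -0.18.

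The 75th percentile scaling moved spots at background too: the median of the negative control spots differed by +0.42 at 10 min and +2.10 at 60 min against the reference, and by +1.67 at 60 min against 10 min. The list's medians were +0.17, +2.07 and +1.86, so its counts under this scaling do not show more phage transcript. Of the 57 measured list members, 5 were higher and 0 lower at 10 min relative to other genes, of which 2 were higher when adjusted over the list alone. The 5 were 2 sk1 genes and 3 TP901-1 genes, given only by number in the files, and none of them was among the genes changed with spike-in scaling. At 60 min 55 were higher and 2 lower against the reference, and 55 and 2 against 10 min, with the same counts adjusted over the list alone. Counted with only probes well above background on all arrays, 17 members had a value, of which 16 were higher and 1 lower at 60 min against the reference. That choice leaves out members that fell to background, so these counts do not stand for the list. With spike-in scaling of these 17, 0 were higher and 2 lower at 10 min, 1 higher and 1 lower at 60 min against the reference, and 2 higher and 1 lower against 10 min, with medians of -0.33, -0.0032 and +0.31. The higher ones were sk1 genes given only by number in the files, and the lower ones were cI in all 3 comparisons and 1 sk1 gene at 10 min. With spike-in scaling and all probes of the 57 members, 0 were higher and 4, 3 and 2 were lower in the 3 comparisons, and 0, 3 and 2 were lower adjusted over the list alone. The lower ones were cI in all 3, ssb (a single-strand DNA binding protein) against the reference at both times, 1 TP901-1 gene without a symbol in all 3 and 1 sk1 gene without a symbol at 10 min. The gene cI was given by the rule for named genes, which picks by the size of the change in these data. The others were singled out after their values were seen. At 60 min the TP901-1 gene was not well above background, so that its level was at least 11.1-fold lower than in the reference (spike-in scaling, limma adjusted p = 1.0e-06). With 75th percentile scaling that limit was -1.21 on the log2 scale, and with spike-in scaling -3.47. No fold is given for ssb, which was at background at 60 min.

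The list ranked above other genes with camera at the preset correlation, with p = 0.0408 at 10 min, 1.1e-09 at 60 min and 1.1e-10 for 60 min against 10 min in the limma fit. None of these 3 held with a correlation estimated from the list, where the limma p was 0.541, 0.107 and 0.0923. Of the list's members, 40 had no probe well above background on all arrays. Probes at background have no room to fall with the other genes, so the rank of the whole list is not a measure of phage transcripts. With spike-in scaling the list's median was -0.49, -0.19 and +0.25, so at both times against the reference its median and the test relative to other genes differ in sign. With the replicate number as a block the limma p at 10 min was 0.0527, and without 10 min replicate 1, 10 min replicate 2 or reference replicate 3 it was 0.240, 0.152 and 0.188. With the slide row as a block the limma p was 0.0051, 2.6e-09 and 3.6e-09. Within row 1 it was 0.0011 (1 array against 2), 2.0e-09 (1 against 2) and 2.1e-09 (1 against 1), and within row 2 it was 0.0131 (2 against 1), 1.8e-09 (1 against 1) and 4.9e-09 (1 against 2).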

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

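The tests of labelling yield, of a detector plateau, of RNA breakdown, of a lower common level and of the floor subtracted from every signal were chosen only after the result was seen; the tests of background probes, of signal level, of array position and of other splits were chosen before.

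The lower chromosomal signal against the spike-ins was weighed first. A lower labelling or hybridisation yield would lower the spike-ins too, and their mean changed by -0.13 at 60 min (-0.29 and +0.03 without 60 min replicate 1 or 2) where the chromosomal median changed by -2.22 (-1.83 and -2.61), which argues against it for steps after the spike-ins were added. Less sample RNA per spike-in, with a fall of rRNA hidden by a detector plateau, stays open: the 9 tRNA probes as bright as rRNA in the reference changed by a median of -0.9996, at the edge of what had been set to exclude it, and unscaled rRNA medians lay close to the brightest spike-in. The dimmest 10% of rRNA probes changed by a median of +0.28, which decides nothing. They reached 2.66 in the reference on the log2 scale against the spike-ins, close to the rRNA median of 2.85. The 14 dimmest rRNA probes, at 0.75 to 2.22 there, changed by -2.21 to -1.82, which goes with a hidden fall. General breakdown of the RNA, for which the files hold no measure of integrity (the rRNA median changed by +0.26, or +0.47 and +0.05 without 60 min replicate 1 or 2), and a biological loss of messenger RNA during starvation stay open too, and these cannot be told apart here.

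The genes higher at 60 min under percentile scaling were weighed next. With only probes well above background on all arrays 48.9% of genes were higher, against 48.3% with all probes, which decides nothing, as that choice leaves out probes that fell. With the floor subtracted from every signal, 670 of the 816 higher genes with every probe above it (82.1%) were still called higher, which argues against the floor as the cause in these, while it stays open for the other 146 and for 386 higher genes with a probe at or below it, as the share of 36.8% in brighter and 59.8% in dimmer genes goes with it. A lower common level of all genes, which this scaling removes, stays open: 3.66% of these genes were also higher against the spike-ins, but both scalings differ by 1 shift for all genes (2.26 on the log2 scale), which fixes that share, so it decides nothing. Other values go with a lower common level. Before scaling, the chromosomal median intensity was 2062 and 2816 at 60 min, against 11687 to 12990 in the reference. The mean spike-in signal changed by -0.13 there, and percentile scaling moved the negative control spots by +2.10. These values do not show which of the genes rose themselves.

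Neighbouring locus tags changed together, with a correlation of 0.67 between the 60 min fold changes of neighbours, where shuffled tags reached at most 0.11. If a trend with signal level made this correlation, removing the trend would lower it, and it was 0.62 after removal. Neighbours were not placed closer on the array than shuffled tags beyond chance, at percentile 11 of 100 shuffles. Shared transcripts of neighbouring genes are a candidate explanation, as a hypothesis found and examined on the same data.

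The count of 1143 genes for 10 min against reference came from 1 of the 10 splits of the 6 arrays, and the highest count of the other splits was 0. The splits are too few for a share under 0.05. For the phage list, 7 of the 10 splits gave as small a p as the 0.0408 of the real one, the smallest other being 2.1e-18. The split that followed the slide row gave 0.00056, where the p with the row as a block was 0.0051. The preset correlation was 0.01, and the correlation estimated for the list was 0.257.

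Several genes were singled out because their change at 60 min differed from that at 10 min, by the limma comparison of both times. With 75th percentile scaling the differences were +2.48 for llmg_2311 (spike-in +0.87), +1.16 for llmg_1848 (spike-in -0.46), -1.58 for llmg_0973 (spike-in -3.19), -0.62 for cI (spike-in -2.23, with a limit of -1.89 for its probes at background), +1.95 for dut (spike-in +0.35) and +1.86 for rus (spike-in +0.25). The cI call (limma adjusted p = 0.0330) was lost without 60 min replicate 1 (0.0902), 60 min replicate 2 (0.116), 10 min replicate 2 (0.0609) or reference replicate 2 (0.0525). It was also lost with normexp (-0.09, limma adjusted p = 0.687), a trended and robust variance (0.0536), only the groups compared (0.0721) and within row 1 (0.102, 1 array against 1) or row 2 (0.133, 1 against 2), where few arrays can lose a call by themselves. For llmg_2311, llmg_1848, dut and rus the spike-in values did not pass the test, and negative control spots differed by +1.67 under the percentile scaling.

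Signal also appeared in spots outside the gene comparisons. The 5 spots named AM_new, whose meaning the files do not give, were well above background in 92.5% of spot and array values, where the 77 negative control spots were in 3.25%. Their median differed by -0.11 between starved and reference arrays against the spike-ins (exact p = 0.857, adjusted p = 0.857), and of 4 tested probes 4 were higher at 60 min with percentile scaling and 0 with spike-in scaling. Among the ETG control spots, the brightest kind had a mean log2 signal of 12.91. No group held 4 to 10 arrays, so no test for a single array far from its group was made.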

How the results depend on the processing

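The tests chosen only after the result was seen were rRNA scaling, kept outlier spots, only detected probes, single slide rows and those of the class signals and of the limits of falls. Counts of changed genes stayed within 1.5 times the reported ones except as given here, and leaving out an array gave 874 to 1217, 1775 to 2007, 1352 to 1730 and, at both times, 658 to 886. Row 2 of the slide alone gave 192 genes at 10 min, 1287 at 60 min and 162 at both times, from 1 or 2 arrays per group. rRNA scaling gave 1370 at both times, and the cause was not tested. These counts are totals and do not rate the split into higher and lower genes, which moved with the scaling. At 60 min against the reference the split was 1202 and 775 as reported, and 44 and 1741 with spike-in scaling. Of the 1977 reported calls, 819 were called in the same direction there. At 60 min against 10 min the split was 1161 and 584 as reported, and 3 and 1431 with spike-in scaling. The replicate block gave 1456, 2067, 1870 and 1075 genes. Where 1 array of a group was left, it was assumed to vary like the other groups.

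The median chromosomal change was -1.38 and -2.61 in row 1 and -1.83 at 60 min in row 2 (1 or 2 arrays per group). Leaving out an array gave -1.03 to -0.61 at 10 min, -2.61 to -1.83 at 60 min and -1.74 to -0.97 between them. At 60 min against the reference it gave -1.90 to -0.95 for pseudogenes, -2.32 to -1.71 for tRNA, +0.0489 to +0.47 for rRNA and -0.29 to +0.0282 for the unscaled spike-in mean.

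The phage list at 10 min lost its call, with p = 0.290 (quantile), 0.0649 (75th percentile of detected probes), 0.560 (spike-in), 0.779 (authors' table), 0.0867 (genes above background on all 8 arrays), 0.0527 (replicate block), 0.541 (estimated correlation), 0.225 (fry), 0.584 (rRNA), 0.0673 (outlier spots kept) and 0.105 (detected probes) from limma; the cause was not tested. Leaving out an array gave 0.00033 to 0.240, and at 60 min 3.9e-11 to 1.5e-08 against the reference and 3.6e-13 to 1.2e-08 against 10 min. At 60 min an estimated correlation gave 0.107 and 0.0923. The replicate block gave 6.9e-08 and 3.2e-08. The fry test of limma asks whether the list changed, not whether it ranked above other genes, so it rates another question. With percentile scaling the limma fry p was 0.225 at 10 min, and 3.3e-05 and 5.8e-05 at 60 min against the reference and 10 min. With spike-in scaling the limma fry p was 0.0804, 0.257 and 0.541 in the same comparisons.

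Of 392 alternatives for named genes 357 were rated the same, 16 lost the call, 15 gained it and 4 reversed. Of 224 without an array 219 were rated the same. A change of sign with no call in either fit was rated the same too. Among these, dut and rus at 10 min went from +0.38 and +0.48 to -0.28 and -0.18 with spike-in scaling. Against 10 min, llmg_2432 went from -0.13 to as high as +0.13 without an array. The values that reversed with a call in the reported or the alternative fit were -0.46 (spike-in) and -0.50 (rRNA) for llmg_1848 against 10 min. The others were -0.19 and -0.18 (rRNA) for dut and rus at 60 min against the reference. The log2 limit of the fall of the TP901-1 gene was -3.73 with rRNA scaling, -1.21 with the 75th percentile and -3.84 to -3.10 without an array. At 60 min against the reference these were -6.84, -4.32 and -7.16 to -5.996 for llmg_0973, -5.27, -2.74 and -5.41 to -4.66 for llmg_1848 and -3.17, -0.65 and -3.19 to -2.63 for cI. Spike-in and rRNA scaling shift all genes of an array alike by construction. The detector plateau left open for rRNA would affect rRNA scaling too, so its values are not independent support for the spike-in ones. Signal near background limits the phage genes.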

Other observations

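The tests of rRNA probes, of repeats along their numbers and of a gradient along the locus tags were chosen only after the result was seen.

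Most rRNA probes moved together, and 14 of 574 did not. Against the spike-ins these 14 fell at both times, by values of -1.91 to -1.31 at 10 min and -2.21 to -1.82 at 60 min, where the others at 60 min lay between -0.16 and +0.40. They were the dimmest of the rRNA probes. Along the probe numbers the changes repeated best at a distance of 89 among 131 distances (r = 0.82, across probes, the next best being 0.43), and 12 of the 14 had a partner at that distance.

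The median of the pseudogene probes minus the chromosomal median was larger by 0.79 at 60 min than in the reference (exact p = 0.10, the smallest possible with 2 arrays against 3). Of 366 pseudogene probes, 291 were higher and 26 lower at 60 min relative to other probes with limma, and 3 were higher and 174 lower against the spike-ins. Of 224 tRNA probes, 1 was higher and 76 lower at 10 min and 112 were higher and 24 lower at 60 min relative to other probes, where spike-in scaling gave 0 higher and 129 and 201 lower.

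A gradient of the 60 min fold change from the first locus tag towards the middle of the numbering was tested as a hypothesis. The correlation with the distance from the first tag was 0.0056 over genes, within the middle range of circular shifts, -0.02 to 0.02, so no gradient was seen.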
